A study of Mus musculus with 10 samples.

How the data were processed

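The values are raw read counts per gene symbol, 1 column per library, as deposited by the submitters, with no normalization applied. Per the submitters' processing notes, stranded libraries made with NEB Ultra Directional chemistry from total RNA (Qiagen Micro RNeasy, checked on a Bioanalyzer) were sequenced as 75-base single reads on a NextSeq 500. Per the same notes, reads were aligned to mm10 with STAR 2.3.1z4 and counted with featureCounts. DESeq2 is named there without a step. The annotation release and the settings for strand and for reads with several alignments are not given in the sources used here. The table held 38720 symbols; 35654 matched GENCODE M21 (GRCm38) by symbol, 1765 through an older symbol and 1301 not at all. Total counts per library ran from 21762668 to 39517946.

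Genes were filtered with filterByExpr, scaled with TMM factors and fitted with the quasi-likelihood test of edgeR 4.0.16 (robust spread), with 1 coefficient for each of the 3 groups and all 10 libraries in 1 fit. This left 16340 tested genes in 3 comparisons. Benjamini-Hochberg adjustment ran over all tested genes of a comparison, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F, and scaled counts (CPM) use TMM-scaled library sizes. Every adjusted p for a gene comes from edgeR unless another tool is named. Lists of at least 3 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 34 lists. Adjusted p-values in the text for lists come from camera. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.

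The comparisons, the test, the threshold, the gene lists, most alternatives and the rule for named genes were chosen before the data were examined. The 34 lists cover Lin28 and microRNA processing genes, let-7 targets, Hox paralog groups 1 to 9, 10 to 12 and 13, tail bud progenitor, presomitic, somite, muscle, cartilage, mesenchyme, neural progenitor, neuron, neural crest, notochord and floor plate, gut endoderm, surface ectoderm, red blood cell, endothelial and macrophage genes, Wnt, FGF, retinoic acid and BMP targets, cell cycle, p53 target, ATF4 stress, glycolysis, oxidative phosphorylation, mitochondrially encoded, ribosomal protein, handling stress, imprinted growth and sex-linked genes. The rule names Lin28a, Lin28b and Foxd1 in every comparison. It adds the 10 largest rises and 10 largest falls of each comparison among genes past the threshold whose groups do not overlap and whose mean reaches 1 CPM in a group, leaving out unnamed and predicted symbols. It also adds up to 4 members of each list with the smallest p between the Lin28a-induced and no-Cre libraries, all Hox13 genes, and 5 genes per direction that changed against both controls. Other genes named were chosen after their values were seen: Pmaip1, Bax, Trp53inp1, Zmat3, Sesn2, Mdm2, Bbc3, Igf2bp1, Dna2, Tgfbr1, Hmga2, T, Aen, Ei24, Bak1, Tnfrsf10b, Zfp365, Tarbp2 and Igdcc3 in the first comparison, and the members of the lists named against wild type other than Trim71, Eda2r and Cdx1.

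let-7 seed matches of 7 bases (or 8) were searched in annotated 3′ UTRs of at least 30 bases, available for 20405 symbols. Genes that share at least 1% of their 32-base words with another annotated gene were left out in 1 alternative setting. The text gives the share for some genes only, so a gene without one can exceed 1%, such as Cdkn1a (3.16%) and Krt5 (12.3%). GC content and length were available for 16161 of the 16340 tested genes (98.9%), and offsets used a lowess span of 0.2. A floor of 3 counts over the group was used where all libraries of a group were at 0. Alternatives were DESeq2 with its own size factors, DESeq2 size factors in edgeR, limma-voom, no filter, a filter of 1 CPM in 3 libraries, only the groups compared, a sex covariate, libraries without globin and mitochondrial genes, an absolute log2 fold change of at least 0.5, a spread that is not robust, pooled controls and leaving out each library in turn. Chosen after the data were examined were GC and length offsets, genes without shared sequence, red blood cell and macrophage covariates, and the tests without Lin28a.

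In negative binomial counts simulated with the dispersions edgeR estimated here, with 200 changed genes, the edgeR test found 37 of 48 genes changed 2-fold, 28 of 48 changed 1.5-fold and 19 of 50 changed 1.3-fold between the Lin28a-induced and no-Cre libraries, with 8 false calls among 16102 genes. Against wild type it found 40 of 50 genes changed 2-fold (Lin28a-induced) and 37 of 49 (no-Cre), with 7 and 10 false calls. A shifted list gave adjusted p = 3.33e-10, 9.81e-13 and 1.04e-12 in the 3 comparisons and an unshifted list 0.829, 0.653 and 0.623.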

Results

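RNA sequencing measured gene expression in the microdissected tail bud, the posterior growth zone of the embryo, of mice at embryonic day 12.5. The series asks what the Lin28/let-7 pathway does while the caudal body axis lengthens. Lin28a encodes an RNA-binding protein that blocks the maturation of let-7 microRNAs, and Lin28b encodes its paralog. The 10 libraries formed 3 groups. The Lin28a-induced group (replicates 2, 3, 4 and 5, n = 4) carried a doxycycline-responsive Lin28a transgene, a Cre-activated rtTA allele and a FoxD1-Cre allele, and received doxycycline. The no-Cre control group (replicates 6, 7 and 8, n = 3) carried both transgenes without Cre and also received doxycycline. The labels of the wild-type group (replicates 1, 2 and 3, n = 3) name neither a transgene nor doxycycline.

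The Lin28a-induced libraries held 29898412, 34261276, 32126966 and 39517946 counts in replicates 2 to 5. The no-Cre libraries held 38893332, 33763406 and 29300166 in replicates 6 to 8. Wild-type replicates 1, 2 and 3 held 25316537, 24240725 and 21762668. The wild-type libraries also stood apart in composition. Mitochondrially encoded transcripts took 2.19% ± 0.442 (SD, n = 3) of their counts. The share was 0.562% ± 0.126 (n = 4) in the Lin28a-induced and 0.574% ± 0.0434 (n = 3) in the no-Cre libraries. Annotated pseudogenes took 0.308% ± 0.0286 of the wild-type counts, against 0.124% ± 0.00371 and 0.128% ± 0.00158. The first principal component carried 57.0% of the variance and separated the wild-type libraries from the other 7. On the second (10.7%), wild-type replicate 2 stood at 52.3, against -35.6 and -26.8 for replicates 1 and 3. Correlations of log2 CPM between wild-type replicates were 0.970 to 0.979, against 0.986 to 0.990 within the other groups. The wider spread in wild type enters the 1 fit of all libraries, so a gene that did not pass is not shown to be unchanged. By their counts, Lin28a-induced replicate 5 and no-Cre replicate 7 were female (Xist 28876 and 29382, Ddx3y 0 in both). The other libraries, all of wild type included, were male (Xist 3 to 28, Ddx3y 2471 to 3695). Sex was thus not balanced between wild type and the other groups. The labels give no sequencing date or batch, so a batch that follows the groups cannot be told apart from them. The labels do not state outright that each library came from a different embryo, so p-values measure the spread between the libraries as labelled.

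**Figure D1:**
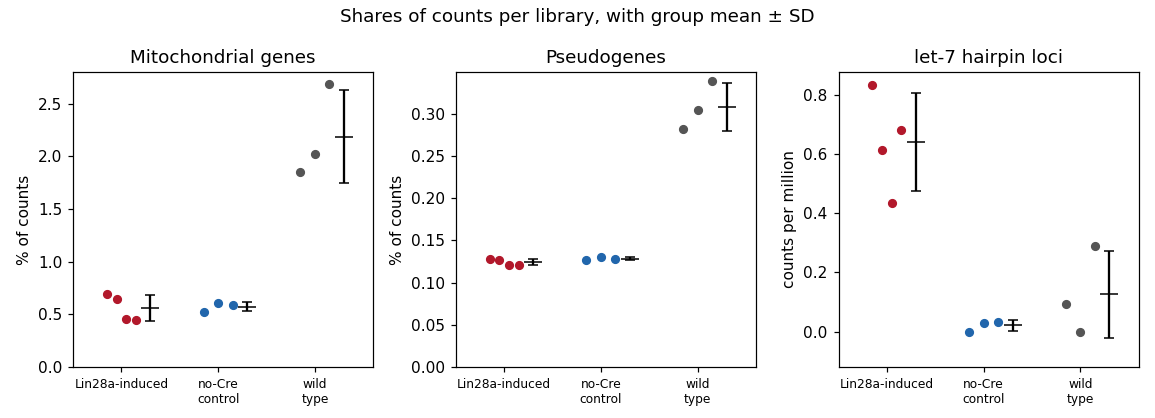
Percent of counts from mitochondrially encoded genes, percent from annotated pseudogenes, and counts over let-7 hairpin loci relative to the library total, without TMM scaling, in each of the 10 libraries, with group mean and SD. The 3 wild-type libraries sit at 1.85 to 2.69% mitochondrial counts, above the 0.446 to 0.690% of the others, and let-7 hairpin reads are highest in the 4 Lin28a-induced libraries (0.436 to 0.836 unscaled CPM).

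Lin28a reached 664, 605, 750 and 731 CPM (counts scaled to a common library size) in Lin28a-induced replicates 2, 3, 4 and 5. It stood at 5.03, 4.53 and 2.64 CPM in no-Cre replicates 6, 7 and 8, and at 6.16, 5.72 and 4.45 CPM in wild-type replicates 1, 2 and 3. The Lin28a gene lies on chromosome 4 from 134003330 to 134018841 on the minus strand (mm10). Its reads are counted whether they came from the endogenous gene or from the transgene. Lin28a therefore rose 167-fold over the no-Cre control (log2 fold change 7.38 ± 0.21 SE, adjusted p = 2.95e-07) and 126-fold over wild type (6.97 ± 0.21, adjusted p = 7.81e-09). The 2 control groups did not differ at the threshold (-0.41 ± 0.22, adjusted p = 0.161).

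Lin28a-induced and no-Cre embryos share the transgenes and doxycycline and differ in the FoxD1-Cre allele. Their comparison asks what changes when Cre turns Lin28a on, together with any effect of that allele itself. The clearest change beyond Lin28a was a joint rise of p53 target genes. Eda2r, a gene of the TNF receptor family, rose 4.37-fold, from 7.73 ± 1.24 CPM (SD, n = 3) to 33.7 ± 3.02 CPM (n = 4). Cdkn1a, which encodes the cell cycle inhibitor p21, rose 2.18-fold, and the let-7 target Trim71, an RNA-binding ubiquitin ligase of early progenitors, rose 2.31-fold. Nsg2, a neuronal vesicle protein gene, fell to 0.403 of its no-Cre level. On mm10, Eda2r lies on chromosome X (97333840 to 97377216), Trim71 on chromosome 9 (114507133 to 114564369), Cdkn1a on chromosome 17 (29090976 to 29100727) and Nsg2 on chromosome 11 (32000463 to 32059202). Among 16340 tested genes, 476 passed the threshold, 288 higher and 188 lower in the Lin28a-induced libraries, with a median absolute log2 fold change of 0.34 and only 8 rises and 12 falls of at least 2-fold. At an unadjusted p under 0.05 there were 2658 genes.

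**Figure D2:**
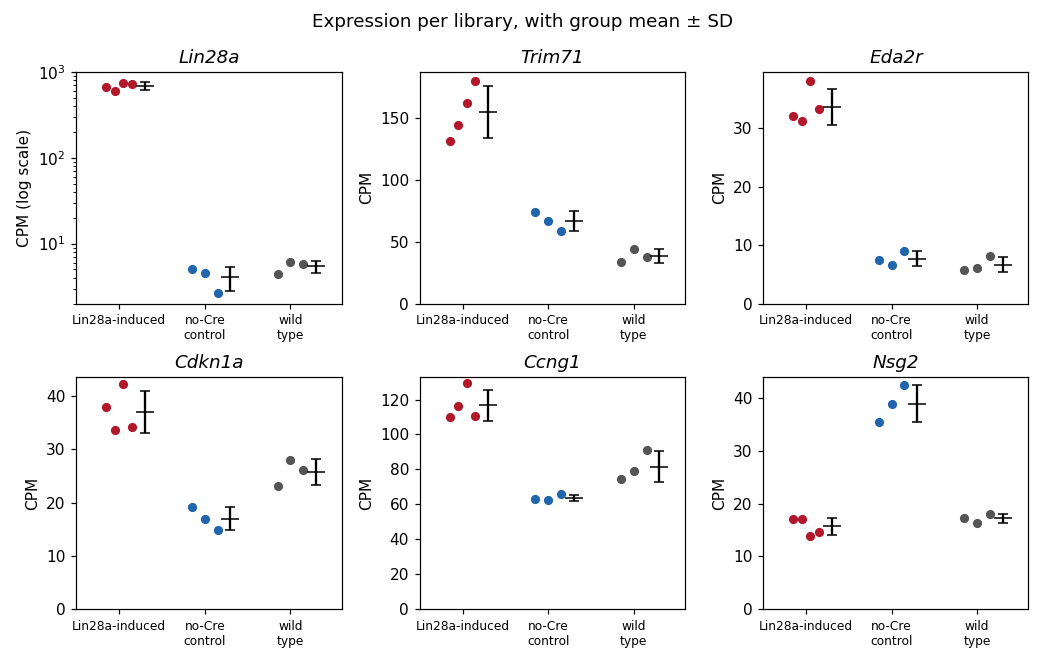
Scaled counts (CPM) of Lin28a (log axis), Trim71, Eda2r, Cdkn1a, Ccng1 and Nsg2 in each library, with group mean and SD. Eda2r averages 33.7 in the 4 Lin28a-induced libraries and 7.73 in the 3 no-Cre libraries, while Nsg2 averages 39.0 in the no-Cre libraries against 15.7 in the Lin28a-induced and 17.2 in the wild-type libraries.

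Of the 11 p53 targets fixed as a list, 9 rose, none fell and 2 did not pass the test, and 9 also passed when adjusted over the list alone. Eda2r rose by 2.13 ± 0.13 on the log2 scale (adjusted p = 2.01e-06). Ccng1, a cyclin G gene, rose by 0.87 ± 0.07 (117 ± 9.03 against 63.7 ± 1.74 CPM, adjusted p = 4.55e-05). Cdkn1a rose by 1.12 ± 0.11 (37.0 ± 3.98 against 17.0 ± 2.15 CPM, adjusted p = 9.23e-05) and Phlda3, a repressor of AKT signalling, by 0.90 ± 0.11 (36.4 ± 3.22 against 19.4 ± 1.47 CPM, adjusted p = 0.00073). The remaining members were singled out after their values were seen. Zmat3 rose by 0.56, Pmaip1, which encodes the apoptosis activator Noxa, by 0.78, Trp53inp1 by 0.76, Sesn2 by 0.40 and Bax by 0.32. Mdm2, the p53 inhibitor, stood at 0.06 ± 0.06 (adjusted p = 0.64) and Bbc3 at -0.03 ± 0.13 (adjusted p = 0.956). The list had a median log2 fold change of 0.76 and passed camera (adjusted p = 2.16e-38, and adjusted p = 0.00245 with an estimated correlation), the only list of the 34 to pass both ways in this comparison. Eda2r, Ccng1, Cdkn1a, Phlda3 and Zmat3 passed in all 7 fits that left 1 library out. Pmaip1 missed the threshold without no-Cre replicate 7 (0.0527) or 8 (0.0528) and Bax without no-Cre replicate 7 (0.0562). Trp53inp1 and Sesn2 each passed in 2 of the 7 fits, with adjusted p up to 0.0998 and 0.157.

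Among 39 let-7 targets, 8 rose, none fell and 31 did not pass; adjusted over the list alone, 11 were higher and 1 lower. Trim71 rose by 1.21 ± 0.12 (155 ± 21.0 against 66.8 ± 7.84 CPM, adjusted p = 0.000699). Fignl2, an AAA ATPase gene, rose by 0.77 ± 0.09 (190 ± 23.9 against 111 ± 11.8 CPM, adjusted p = 0.000901) and Arid3b, a DNA-binding factor, by 0.66 ± 0.09 (324 ± 17.7 against 206 ± 24.6 CPM, adjusted p = 0.00298). E2f5 rose by 0.35 ± 0.06 (adjusted p = 0.00527, but 0.0528 without no-Cre replicate 8). Igf2bp1, Dicer1, Dna2 and Tgfbr1, chosen after their values were seen except Dicer1, rose by 0.46, 0.38, 0.23 and 0.21. Igf2bp1 missed the threshold without no-Cre replicate 7 (0.0775) or 8 (0.0741), Dicer1 passed in 1 of 7 fits without 1 library (up to 0.136), and Dna2 and Tgfbr1 in none (up to 0.222 and 0.162). Hmga2, a chromatin protein often used as a let-7 readout and also chosen afterwards, stood at -0.04 ± 0.07 (566 ± 56.6 against 582 ± 14.5 CPM, adjusted p = 0.851). Lin28b, itself a let-7 target, stood at 35.9 ± 5.31 against 31.3 ± 5.03 CPM (0.20 ± 0.14, adjusted p = 0.553). The list median was 0.01 and its mean 0.08; it passed camera with the preset correlation (adjusted p = 0.000278) but not otherwise (adjusted p = 0.513 with an estimated correlation).

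Of 12 Lin28 and microRNA processing genes 3 rose, namely Lin28a, Dicer1 and Dgcr8 (0.19 ± 0.05, adjusted p = 0.0461, passing in 0 of 7 fits without 1 library); 5 were higher and 1 lower when adjusted over the list alone. The list passed camera (adjusted p = 1.78e-12; adjusted p = 0.121 with an estimated correlation), and without Lin28a it did not (adjusted p = 0.0679). A let-7 seed match in the annotated 3′ UTR was found in 1527 of 14191 searched genes. As a set these genes had a median log2 fold change of 0.01 against -0.00 for genes without a match (camera p = 0.19 over all genes, a test across genes, and p = 0.322 with an estimated correlation). Genes with at least 2 matches (189) gave p = 0.00172 (p = 0.0774 with an estimated correlation), and with Lin28a left out, which carries 2 such matches itself, p = 0.0176 (p = 0.162 with an estimated correlation). Adjusted over the 3 site sets, only the former passed (adjusted p = 0.00517 against 0.0528). The 533 genes with an 8-base match gave p = 0.0344 (adjusted p = 0.0516), and p = 0.107 with an estimated correlation. The seeds of 15 other microRNA families gave p from 0.239 to 0.903. In a linear model adjusted for length and GC content of the 3′ UTR, their t values ran from -1.09 (miR-34) to 2.62 (miR-181). The let-7 seed stood at 1.17 with Lin28a included, so it did not stand out among the families.

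Hox genes, which pattern the body axis, moved little. In paralog groups 10 to 12, 2 of 8 rose, Hoxd10 by 0.34 ± 0.06 and Hoxd11 by 0.24 ± 0.06, and 5 passed adjusted over the list alone. All 8 had positive values, with a median of 0.25 (camera adjusted p = 8.01e-06; adjusted p = 0.167 with an estimated correlation). In groups 1 to 9, 1 of 26 rose, and over the list alone 8 were higher and 1 lower (median 0.16, adjusted p = 0.00012; adjusted p = 0.365 with an estimated correlation). Hoxd10 passed in 4 of 7 fits without 1 library, missing it without no-Cre replicate 6 (0.0887), 7 (0.0705) or 8 (0.074); Hoxd11 passed in 0 of them (up to 0.194). None of the 4 Hox13 genes, which mark the end of axis growth, passed. Hoxa13 stood at -0.08 ± 0.06, Hoxb13 at -0.03 ± 0.20, Hoxc13 at 0.31 ± 0.11 and Hoxd13 at 0.12 ± 0.16, with adjusted p from 0.162 to 0.969 (list adjusted p = 0.626). Hoxc13 passed when the wild-type libraries were left out of the fit (0.000556). Wild-type replicate 2, which enters the spread of the main fit, held 153 CPM of Hoxb13 and 210 CPM of Hoxd13. Wild-type replicates 1 and 3 held 272 and 294 CPM of Hoxb13 and 355 and 345 CPM of Hoxd13.

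The progenitor and lineage lists showed few changes. None of 19 tail bud progenitor genes passed (median 0.07, adjusted p = 0.626), with T, the Brachyury gene, at 382 ± 55.8 against 298 ± 7.90 CPM (0.36 ± 0.30, adjusted p = 0.639). None of 16 presomitic mesoderm and segmentation genes passed (median -0.09, adjusted p = 0.268). Somite genes counted 1 fall among 12, Foxc1 (-0.38 ± 0.09; list median -0.26, adjusted p = 0.0681), and cartilage genes 1 among 13, Col11a1 (-0.61 ± 0.14; median -0.09, adjusted p = 0.0681). Neural progenitor genes counted 1 fall among 9, Sox3 (-0.92 ± 0.18, 2.69 ± 0.421 against 5.12 ± 0.483 CPM; list median -0.35, adjusted p = 0.0257; adjusted p = 0.245 with an estimated correlation). Sox3 missed the threshold without no-Cre replicate 6 (0.0559), 7 (0.0716) or 8 (0.0901), and Foxc1 and Col11a1 with any library left out. In wild type, Sox3 stood at 1.42 to 2.11 CPM and Foxc1 at 92.1 to 132 CPM, below the means of both other groups. Col11a1, at 31.2 to 45.1 CPM there, was not. None of 9 notochord and floor plate genes passed, although all 9 had negative values (median -0.41, adjusted p = 0.0154; adjusted p = 0.365 with an estimated correlation). Mesenchyme genes counted 1 fall among 11, Pdgfra (-0.24 ± 0.06, passing in 0 of 7 fits without 1 library), with 2 higher and 2 lower over the list alone; the median was -0.02, the mean 0.06 and the test pointed down (adjusted p = 0.591). No member passed among 11 neuron genes (median -0.15, adjusted p = 0.573), 9 neural crest genes (0.09, 0.675), 9 gut endoderm genes (-0.01, 0.732), 10 surface ectoderm genes (-0.05, 0.268), 12 endothelial genes (0.05, 0.591) or 10 muscle genes (median 0.03, mean -0.01, test up, 0.822). Red blood cell genes had 10 negative values and none passed (median -0.56, adjusted p = 0.0124; adjusted p = 0.794 with an estimated correlation); their share of the counts was 0.519% ± 0.106 against 0.772% ± 0.193. Adjusted over the list alone, 1 member was higher in each of the neural crest, endothelial and macrophage lists. Macrophage genes had a median of 0.24 with none of 10 passing (adjusted p = 0.043; adjusted p = 0.794 with an estimated correlation).

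Growth and metabolic genes moved by small amounts. Among 14 imprinted growth genes 3 fell: H19 (1812 ± 48.3 against 2483 ± 51.0 CPM, -0.46 ± 0.09), Igf2 (1282 ± 70.5 against 1585 ± 14.7 CPM, -0.31 ± 0.07) and Igf2r (363 ± 42.0 against 468 ± 13.8 CPM, -0.37 ± 0.09). All 14 had negative values (median -0.18, adjusted p = 0.000312; adjusted p = 0.357 with an estimated correlation). Igf2 and Igf2r each passed in 1 of 7 fits without 1 library and H19 in 0 (adjusted p up to 0.136, 0.184 and 0.102), and Igf2 shares 61.9% of its sequence words with another annotated gene. Glycolysis genes counted 1 fall among 14, Pgk1 (-0.31 ± 0.07), and 3 over the list alone (median -0.12, adjusted p = 0.00429; adjusted p = 0.794 with an estimated correlation). Pgk1 shares 54.7% of its words with other genes and passed in 1 of 7 fits without 1 library. Among 11 ATF4 stress response genes 1 rose, the folate enzyme gene Mthfd2 (0.39 ± 0.07; list median -0.07, adjusted p = 0.675), though not without no-Cre replicate 7 (0.103) or 8 (0.0875). Retinoic acid genes counted 1 rise, Crabp2 (0.32 ± 0.07, passing in 2 of 7 fits without 1 library), and 1 fall among 9 (median -0.19, adjusted p = 0.268); over the list alone 1 was higher and 2 lower. No member passed among 22 cell cycle genes (median 6.24e-05, mean -0.02, adjusted p = 0.626), 18 oxidative phosphorylation genes (-0.01, 0.593), 7 mitochondrially encoded genes (-0.08, 0.626), 11 handling stress genes (-0.14, 0.732), 10 BMP targets (0.09, 0.273), 10 FGF targets (median 0.01, mean -0.01, test down, 0.822) or 5 sex-linked genes (median 0.10, mean -0.04, 0.914). The same held for 10 Wnt targets (-0.17, adjusted p = 0.187), of which 2 were lower over the list alone. Of 38 ribosomal protein genes none passed, with a median of -0.06 (adjusted p = 0.0123; adjusted p = 0.889 with an estimated correlation).

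**Figure D3:**
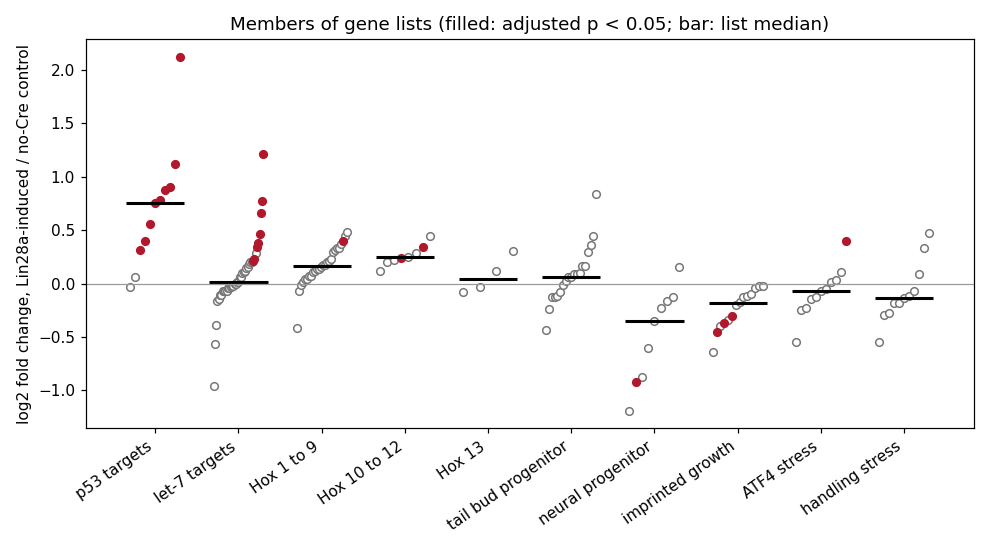
Log2 fold change between the Lin28a-induced and the no-Cre libraries for each tested member of 10 gene lists, with members past the adjusted threshold filled in red and a bar at each list's median. The p53 targets have a median of 0.76 and 9 of 11 members past the threshold, while let-7 targets have a median of 0.01 with 8 of 39 past it.

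Outside the lists, among genes of at least 1 CPM in a group whose libraries do not overlap, unnamed and predicted symbols left out, the largest rises after Lin28a and Eda2r were Fam212b (1.69 ± 0.23, 3.07 ± 0.210 against 0.957 ± 0.327 CPM), Lgals3bp (0.94), Trim6 (0.89) and Ankrd45 (0.88). Under the same limit the largest falls were Nsg2 (-1.31 ± 0.09, 15.7 ± 1.66 against 39.0 ± 3.55 CPM, adjusted p = 6.13e-06), Pkd1l1 (-1.31), the secreted glycoprotein gene Olfm4 (-1.21 ± 0.11, 5.77 ± 0.502 against 13.4 ± 0.676 CPM, adjusted p = 6.68e-05), Brinp2 (-1.13), the neural transcription factor gene Pou3f3 (-1.10), Prr15 (-1.08), the neurotrophin receptor gene Ntrk3 (-1.08), Dgkg (-1.05), Agtr1a (-1.04) and Kcnn3 (-1.03). In wild type, Olfm4 stood at 4.13 to 4.69 CPM, Brinp2 at 1.55 to 1.70 and Pou3f3 at 0.406 to 0.636. Agtr1a stood there at 0.367 to 0.636 CPM and Kcnn3 at 0.755 to 1.88. Each lay below its Lin28a-induced mean, so these genes fell against the no-Cre control but not against wild type. Wild-type values ran from 0.730 to 2.25 CPM for Pkd1l1, 1.14 to 1.97 for Prr15, 1.06 to 2.56 for Ntrk3 and 1.87 to 3.86 for Dgkg. Each range held the Lin28a-induced mean (0.923, 1.75, 2.15 and 3.12 CPM), so a fall against wild type is not shown for these genes. Nsg2, at 16.3 to 18.1 CPM in wild type, lay above its Lin28a-induced mean but did not pass the threshold against wild type (-0.14). Against the no-Cre control, Fam212b, Nsg2, Olfm4 and Brinp2 passed in all 7 fits without 1 library. Trim6 passed in 5, missing the threshold without no-Cre replicate 7 (0.0592) or 8 (0.0793), Pou3f3 in 4, Dgkg and Agtr1a in 3 each, Lgals3bp, Prr15, Ntrk3 and Kcnn3 in 1 each, and Pkd1l1 and Ankrd45 in 0, and the highest adjusted p over these genes was 0.21. Foxd1, the locus that drives Cre, stood at 5.28 ± 1.56 against 8.75 ± 1.28 CPM (-0.72 ± 0.19, adjusted p = 0.0572). It passed without Lin28a-induced replicate 5 (0.00786). It also passed in a DESeq2 Wald test (0.00912), with limma-voom (0.0346), without a filter on low counts (0.0364), with only the 2 groups in the fit (0.0452) and with GC and length offsets (0.0354).

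The count of 476 depended on the libraries and the fit. It was 952 with a DESeq2 Wald test, 1791 when the wild-type libraries were left out of the fit, 300 with embryo sex and 281 with blood and macrophage marker levels as covariates, 293 among genes without shared sequence and 114 with a log2 fold change of at least 0.5. The excess of rises was not kept in every setting, with 491 higher and 461 lower with DESeq2, 912 and 879 without the wild-type libraries, 57 and 57 with the fold threshold, and 125 and 156 with the marker covariates, under which 162 of the 476 genes passed. The count was 304, 291, 174 and 209 without Lin28a-induced replicates 2, 3, 4 and 5, and 140, 104 and 106 without no-Cre replicates 6, 7 and 8. Of the 60 named genes that passed, 15 did so in every fit that left out 1 library. Of the 34 lists 12 passed with the preset correlation, while other ways of splitting the same 7 libraries gave up to 14. The neural progenitor list missed the threshold without Lin28a-induced replicate 2 (0.0629), and the let-7 target list with the marker covariates (0.0754). The red blood cell list missed it without Lin28a-induced replicate 3 (0.0752) or no-Cre replicate 6 (0.129), the notochord list without no-Cre replicate 6 (0.0988) and the glycolysis list without Lin28a-induced replicate 3 (0.0544). The ribosomal list missed it without Lin28a-induced replicate 5 (0.123) or no-Cre replicate 6 (0.128). The macrophage list missed it in 5 fits (0.0596 to 0.147), those without Lin28a-induced replicate 2, 4 or 5 or no-Cre replicate 6 or 7.

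The comparison with wild type sets the Lin28a-induced embryos against embryos without the transgenes. Trim71 stood at 155 ± 21.0 CPM (n = 4) against 38.7 ± 5.50 CPM (n = 3), a 4-fold rise (adjusted p = 6.68e-07), and Eda2r rose 5.03-fold (2.33 ± 0.14, adjusted p = 2.53e-08). Lin28b rose 1.65-fold (0.72 ± 0.14, adjusted p = 0.00153). All 10 surface ectoderm genes fell, and all 12 endothelial genes rose, the latter list with adjusted p = 0.412 with an estimated correlation. In all, 8050 genes passed, 3969 higher and 4081 lower, or 49.3% of those tested, and 9088 had an unadjusted p under 0.05. The mitochondrial share of the counts was 0.562% ± 0.126 against 2.19% ± 0.442 beside these changes, and doxycycline, the transgenes and any batch change together with Lin28a here.

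Against wild type, 23 of 39 let-7 targets rose and 7 fell (23 and 7 adjusted over the list alone), among them Fignl2 (1.69 ± 0.10) and Arid3b (1.38 ± 0.10); the list median was 0.24 (camera adjusted p = 9.37e-05; adjusted p = 0.455 with an estimated correlation). Of the p53 targets 7 of 11 rose and none fell, including Zmat3 (0.88 ± 0.08), Cdkn1a (0.52 ± 0.10) and Ccng1 (0.52 ± 0.07), with a list median of 0.33 (adjusted p = 0.000675; adjusted p = 0.28 with an estimated correlation). Pmaip1 (0.12 ± 0.12), Sesn2 (0.04 ± 0.09) and Trp53inp1 (0.01 ± 0.14), which rose over the no-Cre control, did not pass against wild type (adjusted p from 0.421 to 0.979). All 10 surface ectoderm genes fell, such as the keratin gene Krt5 (-2.46 ± 0.13, 34.4 ± 4.84 against 190 ± 21.9 CPM) and the desmoplakin gene Dsp (-1.58 ± 0.06); this list passed with either correlation (median -1.74, adjusted p = 3.25e-23; adjusted p = 0.0132 with an estimated correlation). Gut endoderm genes counted 1 rise and 8 falls among 9 (adjusted p = 6.66e-09; adjusted p = 0.269 with an estimated correlation). All 12 endothelial genes rose, such as the VEGF receptor gene Kdr (1.98 ± 0.25; list median 1.59, adjusted p = 1.36e-07; adjusted p = 0.412 with an estimated correlation). Presomitic genes counted 10 rises among 16, such as Pcdh8 (2.29 ± 0.16; adjusted p = 0.000191; adjusted p = 0.269 with an estimated correlation), and tail bud progenitor genes 8 rises among 19, such as the caudal homeobox gene Cdx1 (3.77 ± 0.42; adjusted p = 0.00138; adjusted p = 0.705 with an estimated correlation). All 7 mitochondrially encoded genes fell (median -2.03, adjusted p = 4.18e-09; adjusted p = 0.269 with an estimated correlation), as did 36 of 38 ribosomal protein genes, with 1 rise (median -0.49, adjusted p = 4.38e-16; adjusted p = 0.412 with an estimated correlation). The microRNA processing list (8 up, 1 down of 12, adjusted p = 6.76e-06; adjusted p = 0.269 with an estimated correlation), FGF targets (7 up, 1 down of 10, adjusted p = 0.0283; adjusted p = 0.705 with an estimated correlation), macrophage genes (7 up of 10, adjusted p = 0.0386; adjusted p = 0.705 with an estimated correlation) and glycolysis genes (1 up, 10 down of 14, adjusted p = 0.00411; adjusted p = 0.705 with an estimated correlation) also passed with the preset correlation. Among the lists that did not pass, ATF4 targets had a median of -0.05, a mean of 0.05 and a test pointing up, neural crest genes a median of 0.04 and a test pointing down, retinoic acid genes a median of -0.02 and a test pointing up, and sex-linked genes a median of -0.79, a mean of 0.93 and a test pointing down. Hox genes counted 9 rises and 4 falls among 26 in groups 1 to 9, 2 and 2 among 8 in groups 10 to 12, and 1 rise among 4 in group 13, and none of these lists passed. Adjusted over the list alone, presomitic genes counted 11 rises, microRNA processing genes 10 and 1 fall, FGF targets 8 and 1, and macrophage genes 7 and 1, with the other lists named here as given.

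Among the largest rises over wild type, Trim12a had 0 counts in the wild-type libraries and was at least 49.9-fold higher in the Lin28a-induced libraries (floor of 3 counts over the group, a bound that covers counting error only), with 15.4% of its words shared with other genes. Hba-a2, an alpha globin gene, rose from 0.368 ± 0.347 to 125 ± 25.2 CPM but shares 92.4% of its words with its neighbour, so the counts are uncertain. Grin2c rose by 4.86 ± 0.49, Adra2b by 4.22 ± 0.33, the erythroid genes Hemgn by 3.79 ± 0.73 and Gfi1b by 3.77 ± 0.58, Dnase1l3 by 3.65 ± 0.45 and Klf2, a flow-responsive endothelial factor, by 3.54 ± 0.34. Among the falls, Grik3, a kainate receptor gene, was down to 0.444 ± 0.158 CPM (-4.86 ± 0.28), Wnt2 from 2.37 ± 0.676 to 0.0847 ± 0.0445 CPM, Otogl by -4.35 ± 0.33 and Ifi202b from 1.78 ± 0.576 to 0.0644 ± 0.110 CPM. Cxcl5 (3.59 ± 0.928 CPM in wild type) and Col6a5 (1.04 ± 0.136) were near 0 in the Lin28a-induced libraries, and Ccnb1ip1, with 12.1% shared words, was at least 52.0-fold lower at 0 counts. Vcp-rs (89.2% shared words) and Tpm3-rs7 (78.1%) fell by 4.32 and 4.17 on the log2 scale, and their counts are uncertain for that reason. All 41 named genes that passed in this comparison did so in every fit that left out 1 library, and the macrophage list missed the threshold without Lin28a-induced replicate 2 (0.0539) or 5 (0.0504) or wild-type replicate 1 (0.104) or 2 (0.0607). The count of 8050 was 3911 with a log2 fold change of at least 0.5 and 5067 among genes without shared sequence. With replicate numbers as a block it was 3831, a contrast that rests on the libraries numbered 2 and 3 alone.

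The no-Cre control against wild type measures the background of the transgenes, doxycycline and any other difference between these embryos, without Lin28a induction. All 10 surface ectoderm genes were lower and all 12 endothelial genes higher in the no-Cre libraries, the latter list with adjusted p = 0.519 with an estimated correlation. Krt5 stood at 37.4 ± 6.13 against 190 ± 21.9 CPM (-2.34 ± 0.14) and Kdr at 67.2 ± 3.28 against 16.9 ± 6.66 CPM (adjusted p = 0.000522). Pcdh8, a protocadherin gene of the presomitic mesoderm, was 6.85-fold higher (258 ± 5.72 against 37.7 ± 8.93 CPM, adjusted p = 1.3e-06). Of 16340 genes, 6938 passed, 3435 higher and 3503 lower (42.5%), and 8247 had an unadjusted p under 0.05. The mitochondrial share was 0.574% ± 0.0434 against 2.19% ± 0.442 and the pseudogene share 0.128% ± 0.00158 against 0.308% ± 0.0286 alongside these changes.

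The surface ectoderm list was the only list to pass with either correlation (median -1.71, adjusted p = 3.17e-22; adjusted p = 0.013 with an estimated correlation), with Krt14 at -2.23 ± 0.16, Dsp at -1.60 ± 0.06, Trp63, the master regulator of stratified epithelia, at -1.45 ± 0.12 and Perp at -1.39 ± 0.10. Gut endoderm genes fell in 8 of 9 cases, among them Cdh1 (-1.62 ± 0.11) and Epcam (-1.01 ± 0.12), while Sox17 rose (1.59 ± 0.36; list adjusted p = 5.2e-09; adjusted p = 0.203 with an estimated correlation). Cdh1 and Epcam also mark surface epithelium. Endothelial genes included Cdh5 (1.91 ± 0.30) and Pecam1 (1.40 ± 0.21; list median 1.53, adjusted p = 8.3e-08; adjusted p = 0.519 with an estimated correlation). Presomitic genes rose in 11 of 16 cases, including the Notch modulator Lfng (1.79 ± 0.33) and its ligand gene Dll1 (1.41 ± 0.39; list median 1.48, adjusted p = 7.72e-06; adjusted p = 0.203 with an estimated correlation). Mesp2 varied too widely to pass (32.9 ± 42.5 against 2.37 ± 1.68 CPM, adjusted p = 0.0948), and Dll1 missed the threshold without no-Cre replicate 7 (0.0629) or 8 (0.0576). All 7 mitochondrially encoded genes fell (median -1.94, adjusted p = 5.2e-09; adjusted p = 0.354 with an estimated correlation), and 35 of 38 ribosomal protein genes fell with 1 rise (median -0.46, adjusted p = 2.33e-13; adjusted p = 0.609 with an estimated correlation). Tail bud progenitor genes rose in 8 of 19 cases (adjusted p = 0.00213; adjusted p = 0.709 with an estimated correlation), and FGF targets in 7 of 10 (adjusted p = 0.0178; adjusted p = 0.709 with an estimated correlation), while 8 of 10 BMP targets fell (adjusted p = 0.0347; adjusted p = 0.709 with an estimated correlation). Notochord and floor plate genes rose in 6 of 9 cases, such as Shh (1.47 ± 0.31) and Foxa2 (1.93 ± 0.27), while the ciliogenesis gene Foxj1 fell (-1.53 ± 0.26; list adjusted p = 0.0267; adjusted p = 0.519 with an estimated correlation). Somite genes counted 5 rises and 2 falls among 12 (adjusted p = 0.0347; adjusted p = 0.709 with an estimated correlation). Red blood cell genes counted 4 rises and 1 fall among 10 (adjusted p = 0.0459; adjusted p = 0.709 with an estimated correlation). The embryonic globins Hba-x (1.95 ± 0.47) and Hbb-bh1 (2.82 ± 0.43) and the adult globin Hba-a2 (185 against 0.368 CPM, uncertain for its shared sequence) rose, and the adult globin Hbb-bs fell (-2.54 ± 0.50). Adjusted over the list alone, presomitic genes counted 12 rises, notochord genes 7 and 1 fall, FGF targets 8 and 1, and ribosomal genes 2 and 35, with the other lists named here as given. Among lists that did not pass, medians and means differed in sign for cartilage (-0.02 and 0.08, test up), neural crest (-0.16 and 0.02, test down), retinoic acid (-0.05 and 0.04, test up), handling stress (0.12 and -0.25, test down) and sex-linked genes (-0.89 and 0.97, test down), and neural progenitor genes had a median of -0.26 with a test pointing up. Krt14, Krt5, Trp63 and the other members named here were singled out after their values were seen.

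Genes of the Lin28 pathway and p53 targets also differed between the 2 control groups. Of 39 let-7 targets 21 rose and 5 fell (22 and 6 adjusted over the list alone), with Fignl2 at 0.92 ± 0.10, Trim71 at 0.79 ± 0.13 (66.8 ± 7.84 against 38.7 ± 5.50 CPM) and Arid3b at 0.73 ± 0.10 (list adjusted p = 0.0125; adjusted p = 0.709 with an estimated correlation). Lin28b rose (0.52 ± 0.15, adjusted p = 0.0167) but missed the threshold without no-Cre replicate 6 (0.0634) or 7 (0.0541) or wild-type replicate 3 (0.0541). Of 11 p53 targets 1 rose, Zmat3 (0.32 ± 0.09), and 6 fell, among them Trp53inp1 (-0.75 ± 0.15), Pmaip1 (-0.65 ± 0.13), Cdkn1a (17.0 ± 2.15 against 25.8 ± 2.49 CPM, -0.60 ± 0.11) and Ccng1 (-0.36 ± 0.08). The list as a whole did not pass (median -0.36, adjusted p = 0.364). Phlda3 also fell (-0.41 ± 0.12), though not without no-Cre replicate 7 (0.0508). Eda2r stood at 7.73 ± 1.24 against 6.68 ± 1.26 CPM and did not pass (0.20 ± 0.15, adjusted p = 0.279). Nsg2 was 2.26-fold higher in the no-Cre libraries (1.18 ± 0.10, adjusted p = 1.35e-06), and the Lin28a-induced libraries, at 15.7 ± 1.66 CPM, did not differ from wild type at 17.2 ± 0.896 CPM (-0.14 ± 0.10, adjusted p = 0.256). Foxd1 did not differ between the controls (0.38 ± 0.20, adjusted p = 0.149).

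Under the same limit of 1 CPM, the largest rises of the no-Cre control over wild type were Trim12a (at least 39.6-fold higher), Hba-a2 (185 ± 45.8 against 0.368 ± 0.347 CPM, uncertain for its shared sequence), Grin2c (5.58 ± 0.49), Adra2b (4.99 ± 0.33), Hemgn (4.27 ± 0.74), Gfi1b (4.22 ± 0.59), Disp2 (3.84 ± 0.57), the von Willebrand factor gene Vwf (3.81 ± 0.27), the erythroid antigen gene Rhd (3.66 ± 0.48) and Pkhd1l1 (3.65 ± 0.31). The largest falls were Grik3 (-5.53 ± 0.33), Adh7 (-4.38 ± 0.42), Cdh15 (0.0301 against 1.22 CPM), Lipm (0.0557 against 1.03 CPM), Eif3j2 and Vcp-rs, the latter pair sharing 94.8% and 89.2% of their words with other genes. Cxcl5 stood at 3.59 ± 0.928 CPM in wild type and 0.00869 ± 0.0150 CPM in the no-Cre libraries, and Col6a5 and Ccnb1ip1 were likewise near 0 in the latter. Of the 52 named genes that passed, 49 did so in every fit without 1 library, the exceptions being Lin28b, Dll1 and Phlda3. The red blood cell list missed the threshold without no-Cre replicate 6 (0.0566) or 7 (0.0577) or wild-type replicate 1 (0.147) or 3 (0.108), and the notochord list without wild-type replicate 1 (0.0596). The count of 6938 was 3498 with a log2 fold change of at least 0.5 and 4399 among genes without shared sequence.

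Genes that changed the same way against both controls numbered 325, with 231 higher and 94 lower, against 70.0 and 47.0 expected from the 2 call rates if the calls were independent, and 43 genes passed in opposite directions. The highest were Lin28a, Mirlet7i, Eda2r (2.13 and 2.33), Trim71 (2.31-fold and 4-fold) and Fam212b (1.69 and 1.04). Mirlet7i is the let-7i hairpin locus, with 70 counts in the 4 Lin28a-induced libraries, 2 in the no-Cre and 4 in the wild-type libraries. It rose against both (4.42 ± 0.84 and 3.10 ± 0.77, adjusted p = 0.0138 and 0.00451) and shares 100% of its words with another annotated gene. It missed the threshold against the no-Cre control without replicate 6 (0.0962), 7 (0.0822) or 8 (0.0741). The lowest were Lingo3 (-2.11 and -2.34), the histone genes Hist3h2ba (-0.99 and -1.40) and Hist1h2ac (-0.91 and -1.23), which share 36.2% and 16.6% of their words with other genes, the carbonic anhydrase gene Car3 (-0.96 ± 0.08 and -1.58 ± 0.08) and Lrrc4 (-0.89 and -1.27). Car3 passed against the no-Cre control in all 7 fits without 1 library, Hist3h2ba in 2, Lrrc4 in 1, and Lingo3 and Hist1h2ac in 0. For 205 of the 325 genes the controls did not differ from each other. Both comparisons share the Lin28a-induced libraries. With 2 of these libraries used against each control, 6 ways of halving them gave 65 to 150 shared genes (median 79) against 16.2 to 39.1 expected. In 10 simulations with unchanged groups, at most 2 genes passed the adjusted threshold in either comparison and 0 were shared. At an unadjusted p under 0.05 these simulations shared a mean of 127 genes against 20.4 expected. They drew all groups from the same mean, while the real controls differ, so they do not give a number to set against 325. The count of 325 was 572 with DESeq2, 944 with only the compared groups in each fit, 209 with a sex covariate, 206 among genes without shared sequence and 53 with a log2 fold change of at least 0.5.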

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

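The tests of handling stress, of red blood cells or macrophages, of a strain or batch of the wild-type embryos, and of let-7 hairpin loci against other microRNA loci were chosen or reworded only after the result was seen. So were the splits for genes with at least 2 let-7 matches without Lin28a. Outlying values were sought in the Lin28a-induced group alone, since the other groups hold 3 libraries each. Of 155 values tested there, 6 had 1 library far from the other 3, with a gap that took more of the group's range than Dixon's critical value allows, against 7.75 that chance gives at about 1 in 20.

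Igf2 stood at 1387 CPM in Lin28a-induced replicate 5 and 1238 to 1254 CPM in the other 3. The p53 target gene Aen stood at 75.1 CPM in replicate 3 and 80.2 to 81.0 CPM in the others. Cxcl5 stood at 0.0314 CPM in replicate 4 and 0 in the others. Ifi202b stood at 0.229 CPM in replicate 5 and 0 to 0.0290 CPM in the others. Vcp-rs stood at 8.03 CPM in replicate 4 and 6.17 to 6.28 CPM in the others. Krt5 stood at 41.6 CPM in replicate 5 and 31.4 to 32.6 CPM in the others.

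The rise of p53 targets in the Lin28a-induced libraries was weighed first. Of 35 splits of the 7 libraries, 1 gave a camera p as small in that direction, the real one. The smallest p of the others in that direction was 1.59e-06. In the other direction the largest -log10 p was 12.6, against 39.2 for the real split. The real grouping stood out, but 1 in 35 is the lowest share this test can give. The list was also 1 of 34 tested, so the splits alone do not exclude chance. The tables argue against let-7 sites in the p53 targets themselves (0 of the 9 genes that rose carry a seed match). They argue against handling of the tissue or an ATF4 stress response (the higher of the medians of these lists was -0.072). Other kinds of stress were not tested. The tables also argue against more red blood cells or macrophages in the Lin28a-induced tail buds. With these covariates 9 of 9 targets still passed, at log2 fold changes of 0.32 to 2.19. The median was -0.56 for red blood cell genes and 0.24 for macrophage genes. Cre activity on its own, without Lin28a, stays open, since 0 groups carry Cre without the Lin28a responder, and so cannot be told apart from Lin28a. The rtTA allele is switched on by Cre in the same libraries and was not tested apart either. Nor was the FoxD1-Cre allele itself, in libraries where Foxd1 stood at -0.72 ± 0.19 against the no-Cre control. In addition, p53 activity was not measured, and Pmaip1, Sesn2 and Trp53inp1 were near their wild-type level (0.12, 0.04 and 0.01). The mean log2 CPM of the list was 4.81 to 4.84 in the no-Cre, 4.95 to 5.09 in the wild-type and 5.46 to 5.67 in the Lin28a-induced libraries. Most members, Cdkn1a and Ccng1 among them, were lower in the no-Cre libraries than in wild type, while Zmat3 was higher. The rise was thus smaller against wild type, and whether a low no-Cre level is part of it was not tested.

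The large number of genes that differ from wild type was weighed next. In the comparison of the no-Cre libraries with wild type, 43.2% of genes without shared sequence passed the threshold, which argues against reads from near-identical copies as the whole source. After GC content and length were corrected, 85.8% of the calls remained, which argues against that bias as the whole source. Doxycycline and the transgenes, or another strain, batch, day or dissection of the wild-type embryos, cannot be told apart, since the labels give no batch and place 0 groups with transgenes and doxycycline in one with the wild-type libraries. Of the 35 splits of the Lin28a-induced and wild-type libraries 1, the real one, gave as many as 8050 genes and the highest other gave 1490. The real grouping stood out, but 1 in 35 is the lowest share these splits can give, so they do not exclude chance alone. The 10 splits of the no-Cre and wild-type libraries are too few to decide (6938 genes, highest other 0, with 1 split as large).

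Genes with let-7 seed matches, weighed last, did not pass as a set, and of the 35 splits 3 gave a p as small for all genes with a match (smallest other 0.0413), 1 for genes with at least 2 matches (0.00271) and 4 for the latter without Lin28a (0.00311), all in the direction of a rise. For at least 2 matches a split in the other direction gave a smaller p (-log10 p of 3.19 against 2.76), so chance is not excluded for these sets when both directions count. With Lin28a included, the difference in mean log2 fold change was 0.0124 (95% interval -0.00234 to 0.0271). It was 0.00910 (-0.00609 to 0.0243) after length and GC content of the 3′ UTR were adjusted for, so both intervals include 0. Lin28a, raised through the transgene, adds to both differences. With Lin28a left out, the let-7 heptamer had an adjusted t of 0.58, and 32.8% of all heptamers ranked as high or higher. Among the genes that rose, Lin28a left out, a match was more frequent (57 of 277, 20.6% against 10.8% of all genes searched), with an odds ratio of 1.52 (95% interval 1.11 to 2.08) after length, GC content and expression level were adjusted for, which argues against these as the whole source. Heptamers were also ranked by t in a linear model of whether a gene rose, adjusted for length, GC content and expression level. There 2.70% of all heptamers ranked as high or higher, so let-7 was not alone in this.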

How the results depend on the processing

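Chosen only after the data were examined were the tests with GC and length offsets, with genes without shared sequence, with marker covariates and without Lin28a. Over all settings, named genes kept their direction and side of the threshold in 2928 values, with 358 weaker, 11 stronger and 29 reversed. Lists counted 1760, 61, 31 and 4, and the counts of genes, with the let-7 test, 75 the same, 29 moved and 3 stronger.

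Genes changed between the Lin28a-induced and no-Cre libraries numbered 476, and 952 with a DESeq2 Wald test, 1791 with only the 2 groups compared in the fit, 300 with an embryo sex covariate, 114 with a log2 fold change of at least 0.5, 293 among genes without shared sequence and 281 with red blood cell and macrophage covariates; leaving out 1 library gave 104 (no-Cre replicate 7) to 304 (Lin28a-induced replicate 2). Genes changed the same way against both controls numbered 325, and 572, 944, 209, 53 and 206 under the first 5 of these settings, with 84 to 341 when 1 library was left out. Against wild type, 8050 became 3911 with the fold threshold, 5067 without shared sequence and 3831 with a replicate block on the numbers 2 and 3 of the titles. The labels do not state the meaning of these numbers, and libraries of equal number did not resemble each other more (correlations -0.0306 and -0.0709). The block was fitted without the no-Cre libraries, and leaving these out without a block gave 7145. Only the numbers 2 and 3 occur in both groups, so libraries with other numbers add nothing to the blocked contrast. The 3831 thus rests on fewer libraries than the 7145, which lowers the power to call genes. The 6938 of the no-Cre comparison became 3498 with the fold threshold and 4399 without shared sequence. A fold threshold and fewer genes tested lower these counts by construction. Leaving out the wild-type libraries removes their wider spread (correlations between replicates of 0.970 to 0.979, against 0.986 to 0.990 in the other groups). Whether that accounts for the 1791 genes was not tested, and neither was the cause for the other settings.

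At the preset correlation, the camera test of let-7 seed matches across genes went from p = 0.19 to an unadjusted p = 0.0344 with 8-base matches, 0.00172 with at least 2 matches and 0.0176 with at least 2 matches without Lin28a. Adjusted over the 3 site sets these were 0.0516, 0.00517 and 0.0528, so only the set with at least 2 matches that holds Lin28a passed. With an estimated correlation the unadjusted p was 0.107, 0.0774 and 0.162, and none passed; the cause was not tested.

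With both control groups pooled, Bbc3 (0.11), Hmga2 (0.11), Hoxa13 (0.023), Hoxb13 (0.088), Foxc1 (0.11) and Pdgfra (0.075) turned positive, and the presomitic (adjusted p = 0.00965) and notochord (adjusted p = 0.909) lists turned upward; pooling brings in the wild-type libraries by construction. With the marker covariates Hoxd13 (-0.22) and T (-0.16) turned negative, the tail bud progenitor list turned downward (adjusted p = 0.0411) and the ribosomal list upward (adjusted p = 0.285); the cause was not tested. With 1 library left out, Bbc3 ran from -0.092 to 0.027, Hmga2 from -0.10 to 0.015 and Hoxb13 from -0.071 to 0.041. Against wild type, Trp53inp1 and Sesn2 were near 0 and turned negative: Trp53inp1 with a filter of 1 CPM (-0.014), only the 2 groups (-0.0072), a sex covariate (-0.027), genes without shared sequence (-0.015) and the replicate block (-0.22), and Sesn2 with a sex covariate (-0.0011), the block (-0.14) and GC and length offsets (-0.10). With 1 library left out these ran from -0.11 to 0.23 and from -0.018 to 0.09; the cause was not tested. At this depth, a 1.3-fold simulated change was found for 19 of 50 genes and a 2-fold change for 37 of 48.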

Other observations

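The test of let-7 hairpin loci against other microRNA loci was chosen only after the result was seen. Single genes outside the fixed lists were picked after their values were seen, because they rose between the no-Cre and the Lin28a-induced libraries. They were not tested as a group, and like genes that did not rise were not counted. The nuclease gene Aen rose 1.47-fold (79.2 ± 2.71 CPM, n = 4, against 53.7 ± 3.93 CPM, n = 3; 0.56 ± 0.08) and passed in all 7 fits without 1 library. Ei24 rose by 0.31 ± 0.05, Tnfrsf10b, a death receptor gene, by 0.48 ± 0.10, the replication stress gene Zfp365 by 0.78 ± 0.15 and Bak1 by 0.24 ± 0.06. Ei24 missed the threshold without no-Cre replicate 7 (0.0751) or 8 (0.0741), while Tnfrsf10b and Zfp365 passed in 3 and Bak1 in 0 of the 7 fits. Aen also rose against wild type (0.74 ± 0.08).

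A further pair was picked in the same way. Tarbp2, a partner of Dicer, rose by 0.40 ± 0.07 (46.8 ± 3.40 against 35.4 ± 1.99 CPM) and Igdcc3 by 0.54 ± 0.12. Tarbp2 missed the threshold without no-Cre replicate 7 (0.0592) or 8 (0.0632), and Igdcc3 passed in 1 of 7 fits.

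Reads over let-7 hairpin loci counted 25, 21, 14 and 27 in Lin28a-induced replicates 2 to 5, 0, 1 and 1 in no-Cre replicates 6 to 8, and 0, 7 and 2 in wild-type replicates 1 to 3. Over 10 let-7 loci the Lin28a-induced libraries held 87 counts against 2 in the no-Cre libraries, a 32.7-fold rise (95% interval 8.77 to 274, counting error only). Mirlet7i held 70 of these 87 counts and shares 100% of its words with another annotated gene, so reads from that gene are not separated here. The 645 other microRNA loci held 7874 against 4341 counts, 1.36-fold (1.31 to 1.41), which argues against reads over all short microRNA loci, from library preparation, as the whole source. No biological explanation was tested, and neither mature microRNAs nor the stability of precursors was measured.

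Splits of the libraries were compared with the real grouping. For genes changed between the Lin28a-induced and no-Cre libraries 1 of 35 splits, the real one, gave as many as 476 and the highest other gave 2. The real grouping stood out, but 1 in 35 is the lowest share this test can give. The other splits also mix libraries of both groups, so the splits alone do not exclude chance. For genes changed the same way against both controls it was 1 of 35 splits (325, highest other 1). The other splits called at most 2 genes against the no-Cre libraries, so this adds no evidence to that on the 476 genes. For gene lists past the threshold with the preset correlation, 7 of 35 splits gave as many as the 12 of the comparison with the no-Cre libraries (highest other 14) and 14 of 35 as many as the 13 of the comparison with wild type (highest other 19), so chance cannot be excluded for either. For the lists of the no-Cre libraries against wild type the 10 splits are too few (13 lists, highest other 14, with 6 splits as large).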
